A study of Mus musculus with 31 samples.

How the data were processed

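RNA was measured in the whole brain of 31 female C57BL/6 mice, aged 6 weeks, with 1 Agilent single-colour (Cy3) array per mouse. Each mouse received a tail-vein injection of 200 µl, either oleic acid at 1.2 µl per g of body weight (a model of acute lung injury) or physiological serum, under ketamine and xylazine anaesthesia. Brains were taken 1, 1.5, 3, 4, 18 or 24 h later, and 200 ng of RNA was labelled per sample. The 12 groups held 3 serum and 3 oleic acid mice at 1 h and at 1.5 h, 2 and 3 at 3, 4 and 24 h, and 2 and 2 at 18 h, with no pooling stated in the labels.

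The authors scanned the arrays and extracted them with Agilent Feature Extraction 10.5.1.1, per the file headers. The deposited array files hold Cy3 intensity for each of 62976 spots: a mean spot intensity, a local background intensity and a processed intensity after background subtraction, spatial detrending and replacement of low values, with no normalization between arrays. Per the file headers, the other columns used are flags of 0 or 1 for spots well above background, saturated or non-uniform. The deposited value table is on a log2 scale: on each array it correlated across spots with the log2 mean spot intensity, and its values were quantile-normalized over the 31 arrays. The probe coordinates are those of the array annotation on mm9 (NCBI build 37), and the supplied reference table, which is on a later assembly, was used for gene names only.

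Processed intensities were log2-transformed and divided, on each array, by the 75th percentile of its non-control spots (subtracted on the log2 scale). Non-uniform spots, at most 107 on an array, were set to missing, repeated spots of a probe were averaged, and no spot was saturated. A probe was kept when it was well above background on every array of at least 1 of the 12 groups, which kept 35653 of 55681 probes. Probes were further required to be measured on all 31 arrays, which left 35499. This last requirement was added after the data were examined, because missing spots left some group means undefined, and its effect was tested by keeping those probes. The probe with the highest mean signal stood for each gene, giving 25173 genes or unnamed transcripts, here called genes. Signal over background and the number of arrays limit the precision: between 54.3% and 76.3% of spots were well above background on an array (median 62.2%), and the 75th percentile of processed intensity ranged from 306 to 813.

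A linear model with 12 group means was fitted to each gene with limma 3.58.1 in R 4.3.3, with 19 residual degrees of freedom. Contrasts were the oleic acid minus serum difference at each of the 6 times, its mean over the 6 times, its early (1 to 4 h) minus late (18 and 24 h) difference, an F-test of any difference between times, and an F-test of time in serum mice. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. Log2 differences are given with limma's moderated standard error (SE). Folds given as at least a value are for genes above background on no array of 1 treatment. They are taken over the lowest signal well above background on those arrays, or the gene's own if higher. Such folds hold for the processed intensities only, not for other background corrections.

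Before the data were examined, 35 gene lists for pathways, cell types and brain regions, a panel of 40 genes, the alternatives and the rule for named genes were fixed. Lists were tested at each time and for the mean effect (245 tests) with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated per list, and with fry. The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the test and with separate groups, passing over clone and transcript identifiers. Where fewer than 5 passed, it named the 5 with the smallest unadjusted p as not passing. For the tests across times it named the 10 smallest adjusted p among those passing, plus up to 4 passing members per list, and the panel could be named in every comparison. Other list members, and region and organ genes, were chosen for naming after their values were seen.

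Added after the data were examined were lists for liver, kidney, lung and muscle, a test of time in oleic acid mice, a contrast of serum mice at 4 h and 18 h that lay on the same slide, and a permutation test of list scores. A list score was the mean log2 value of the list's members on an array, and treatment labels were permuted within times, 100000 times and 2-sided.

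The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the deposited value table, no filter, a filter of 24 arrays above background, the mean of all probes of a gene, slide or scan date as a fixed block, slide as a random block, a block by replicate number, limma's arrayWeights, eBayes with trend and robust options, a fit to the arrays of 1 time, a threshold of 1.5-fold, and leaving out each array in turn. Alternatives added afterwards were scores of the cerebellum, pituitary, hypothalamus, liver and lung lists as covariates, fits without the 3 arrays of slide 2, without the 4 arrays with the lowest Gabra6 or without the 3 with the highest Prl, and probes with missing spots kept. The array files place the samples on 5 slides scanned on 2 days.

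The pipeline was tested on simulated arrays in the layout of the real ones, with 100 genes changed by 2-fold and 100 by 4-fold. Each gene kept its real mean and its real spread within groups, with independent noise. Differences between slides or in dissection and correlation between genes were not simulated, so the rates below do not cover them. In the single-time comparisons it recovered between 47% (18 h) and 69% (4 h) of the 2-fold changes and between 85% and 91% of the 4-fold changes, all in the right direction, and for the mean effect it recovered 93% and 99%. For time in serum mice it recovered 80% of 100 genes raised 4-fold at 4 h only. False calls at single times ran from 6 of 138 called (18 h) to 10 of 166 (4 h) and 10 of 149 (24 h). There were 15 of 207 for the mean effect, and 4 false calls for time in serum mice.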

Results

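Gene expression was measured in 31 whole brains, 14 from mice injected with physiological serum and 17 from mice injected with oleic acid, at 6 times from 1 to 24 h after injection. Values below are log2 Cy3 signals relative to the 75th percentile of each array, differences are oleic acid minus serum, and ± gives the SE. Pairs of n are serum mice, then oleic acid mice. The arrays correlated with one another at a mean of 0.978 to 0.988 across genes. The first principal component held 20.5% of the variance, and slide accounted for 84.8% of its spread, time for 49.3% and treatment for 0.41%.

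Transcripts of single brain regions and of other organs varied widely between mice of the same group. Gabra6, a GABA receptor subunit of cerebellar granule cells, ranged from a log2 signal of -7.59 to 2.32, and lay at -7.50 in serum 1 h replicate 1, -7.59 in oleic acid 1.5 h replicate 2, -7.31 in serum 4 h replicate 2 and -6.12 in oleic acid 4 h replicate 3. Prl and Gh, hormones of the anterior pituitary, were near background on most arrays, whereas Prl reached 7.69 in serum 24 h replicate 2, 7.66 in oleic acid 24 h replicate 1 and 7.91 in oleic acid 24 h replicate 3. Hcrt, the hypocretin precursor of the lateral hypothalamus, lay at -0.70 in oleic acid 4 h replicate 3 and at -3.01 in oleic acid 24 h replicate 2, against a median of 2.76. Alb, the serum albumin transcript of liver, spanned from -6.09 to 2.78, and Sftpc, a surfactant protein of lung, from -1.65 to 3.65. These genes were chosen after their values were seen.

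**Figure D1:**
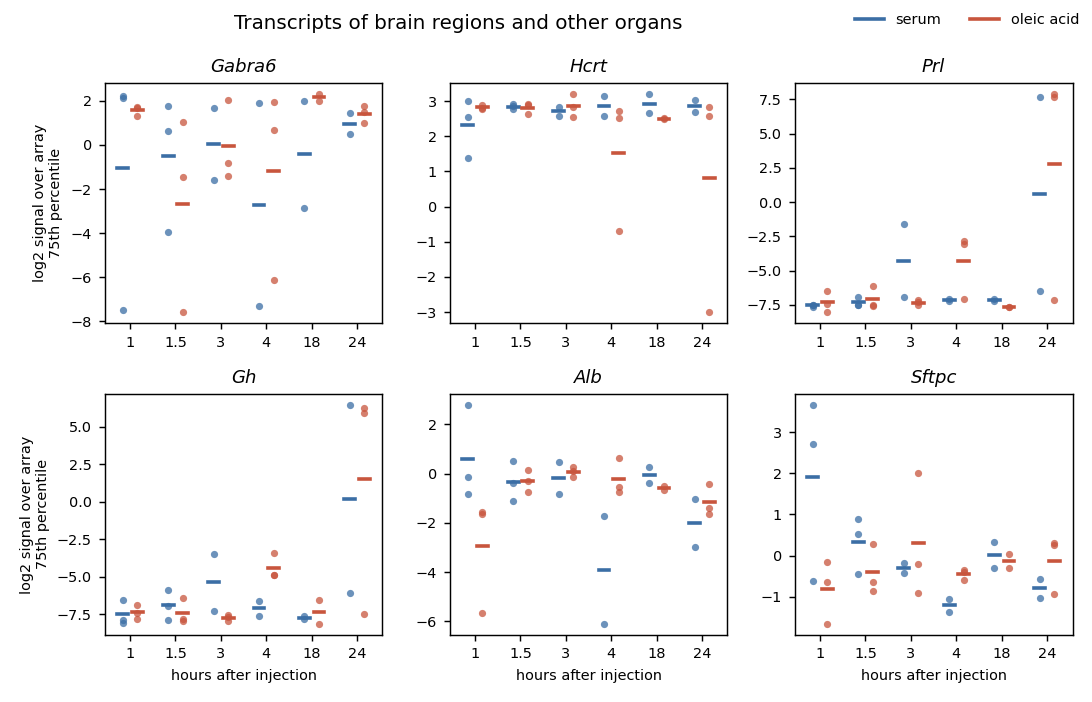
Log2 signal relative to the array's 75th percentile (vertical axis) against hours after injection (horizontal axis) for Gabra6, Hcrt, Prl, Gh, Alb and Sftpc; each point is 1 mouse and each bar a group mean. Gabra6 lay at or below -6.12 in 4 mice from both treatments, and Prl at or above 7.66 in 3 mice at 24 h.

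The comparison at 1 h (n = 3 and 3, all on slide 1) asked how brain transcripts stood soon after oleic acid. Transcripts of red blood cells were the fixed group with the lowest median, at -0.91, with 7 of 10 measured members lower. Hbb-bt, an adult beta globin, differed by -1.56 ± 0.37, Alas2, which starts haem synthesis in erythroid cells, by -1.45 ± 0.35, and Hba-a1, an alpha globin, by -1.27 ± 0.35. Clock genes had 14 of 17 members higher, with Dbp, a clock output factor, at 0.74 ± 0.20 and the period gene Per1 at 0.59 ± 0.22. Choroid plexus markers had 15 of 16 members lower, at a median of -0.31, with the transthyretin gene Ttr at -0.28 ± 0.18. No gene passed limma's adjusted p, and 1221 had an unadjusted p under 0.05, against 1259 by chance. For the lists alone, 5 erythroid, 3 clock, 2 neutrophil and monocyte and 1 reactive astrocyte member passed when p was adjusted over the list alone, and none over all genes. Limma's camera called 9 lists at the preset correlation: erythroid, clock and choroid plexus, and also oligodendrocyte markers (14 of 16 lower, median -0.22), immediate early genes (23 of 30 higher, 0.27), interferon-stimulated genes (22 of 28 lower, -0.20), ion and water transport (13 of 14 lower, -0.14), reactive astrocyte genes (12 of 19 lower, -0.15) and striatum markers (11 of 12 higher, 0.17). With an estimated correlation no call remained, at adjusted p = 0.476 for the erythroid, 0.387 for the clock and oligodendrocyte, 0.632 for the choroid plexus and 0.455 to 0.859 for the other lists.

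The 5 named genes with the smallest unadjusted p at 1 h were transcripts typical of liver, none past the adjusted test. Serpinc1, which encodes antithrombin, differed by -3.92 ± 0.76, and the hepatic transporter Slco1b2 by -2.13 ± 0.44. The aldo-keto reductase gene Akr1c6 differed by -2.60 ± 0.50. The major urinary protein genes Mup5 and Mup4, whose paralogs are close in sequence, differed by -3.26 ± 0.53 and -2.67 ± 0.50. Serpinc1, Slco1b2, Akr1c6 and Mup5 were each above background on 1 of 3 oleic acid and 3 of 3 serum arrays. The sizes of their differences therefore rest in part on oleic acid values near background. Mup4 was above background on 3 of 3 arrays of each treatment. All 21 measured members of the added liver list were lower, at a median of -2.70 (limma camera adjusted p = 0.0543 with an estimated correlation). Alb stood at 2.78 in serum 1 h replicate 2 and at -5.68 in oleic acid 1 h replicate 2. Without serum 1 h replicate 3, 30 genes passed the test.

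At 1.5 h (n = 3 and 3), neutrophil and monocyte markers had the highest list median, at 0.57. Of the inflammatory list, which was not called (16 of 28 members higher, median 0.05; limma camera adjusted p = 0.347), Ccl2, which attracts monocytes, differed by 1.71 ± 0.48, a fold of 3.27, and the interferon-induced chemokine gene Cxcl10 by 0.95 ± 0.42. Neutrophil and monocyte markers had 12 of 14 members higher, with S100a9 and S100a8, subunits of calprotectin, at 0.89 ± 0.41 and 0.75 ± 0.43. Interferon-stimulated genes had 21 of 28 members higher, at a median of 0.26. Cerebellum markers had the lowest list median, at -0.57, with 12 of 12 members lower, though the list was not called (limma camera adjusted p = 0.106), and oleic acid replicate 2 had a Gabra6 level of -7.59. Also lower were the immediate early genes (21 of 30 lower, median -0.34), with the activity-regulated genes Arc at -1.12 ± 0.47 and Fos at -0.75 ± 0.31, and glucocorticoid-response genes (21 of 29 lower, -0.20), with the kinase gene Sgk1 at -0.95 ± 0.34 and Nfkbia, an inhibitor of NF-kB, at -0.72 ± 0.21.

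Genes named by the smallest unadjusted p at 1.5 h were the scaffold gene Cnksr1 (1.76 ± 0.34; at least 1.28-fold higher, above background on 3 of 3 oleic acid and 0 of 3 serum arrays), the nuclear RNA Malat1 (-0.97 ± 0.21), Cdca4 (0.61 ± 0.13), the repressor gene Hic1 (-0.60 ± 0.14) and the RNA polymerase III subunit gene Polr3e (-0.86 ± 0.21). The 2 probes of Hic1 differed in sign (-0.60 and 0.12). None passed limma's adjusted p, and 1331 genes had an unadjusted p under 0.05. Adjusted over the list alone, 2 members passed in each of the neutrophil, inflammatory, immediate early and glucocorticoid lists. Camera called 7 lists at the preset correlation, the neutrophil, interferon, immediate early and glucocorticoid lists and HIF targets (20 of 26 lower, -0.16), heat shock genes (15 of 16 lower, -0.11) and respiratory chain subunits (21 of 24 lower, -0.13), and none with an estimated correlation (adjusted p = 0.455 to 0.809). The groups lay on 3 slides, and with slide as a fixed block 30 genes passed, resting on the 1 serum and 1 oleic acid array of slide 2. Without serum 1.5 h replicate 3, 159 genes passed, and with limma's arrayWeights 1361, where the weights did not converge.

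At 3 h (n = 2 and 3), erythroid transcripts again had the lowest list median, at -1.04, with 9 of 10 members lower. Alas2 differed by -1.32 ± 0.40 and Hba-a1 by -1.26 ± 0.39, which are folds of 2.49 and 2.40. Inflammatory genes had 22 of 28 members higher, at a median of 0.26. Socs3, a feedback inhibitor of cytokine signalling, differed by 0.61 ± 0.19, Il1b, which encodes interleukin 1 beta, by 0.58 ± 0.33, and Cxcl10 by 0.67 ± 0.47. Immediate early genes had 23 of 30 members higher, at a median of 0.27, with Egr1 at 0.60 ± 0.29 and Fos at 0.57 ± 0.35.

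Named by the smallest unadjusted p at 3 h were Txlnb (1.55 ± 0.26; at least 2.06-fold higher, above background on 3 of 3 oleic acid and 0 of 2 serum arrays), Midn (1.07 ± 0.22), the kinase gene Map4k5 (0.76 ± 0.16), Ect2 (1.09 ± 0.23; at least 1.25-fold higher) and Trim30d (0.92 ± 0.21). No gene passed limma's adjusted p, and 1223 had an unadjusted p under 0.05. Adjusted over the list alone, 4 erythroid members passed. Camera called 5 lists at the preset correlation, the 3 above with glucocorticoid-response genes (26 of 29 higher, median 0.17) and respiratory chain subunits (22 of 24 higher, 0.14), and none with an estimated correlation (adjusted p = 0.455 for erythroid and inflammatory, 0.809 to 0.907 for the others). Within slide 3, which held 2 mice of each treatment, the erythroid median was -1.10 and 0 genes passed limma's test. With slide as a fixed block 2 genes passed, Txlnb among them (limma adjusted p = 0.0389). With normexp correction Ect2 and Trim30d changed sign, so the fold given for Ect2 does not hold under that correction.

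At 4 h (n = 2 and 3, all on slide 4), 1 transcript passed the test. It is named by the identifier ENSMUST00000079163, annotated on the array as a vomeronasal type 2 receptor (chromosome 5, 109422719 to 109422778, minus strand), and differed by -3.32 ± 0.42 (limma adjusted p = 0.00235). It was above background on 2 of 2 serum and 0 of 3 oleic acid arrays. On the processed intensities it was at least 2.73-fold lower with oleic acid, but the difference was smaller than that with normexp correction (-0.58). Hypothalamic neuropeptides had 11 of 12 members lower, at a median of -0.56, and in this group oleic acid replicate 3 had an Hcrt level of -0.70. The other called lists were interferon-stimulated genes (21 of 28 higher, 0.13), respiratory chain subunits (21 of 24 lower, -0.10), pericyte and fibroblast markers (13 of 15 lower, -0.18) and unfolded protein response genes (15 of 19 lower, -0.16). These 5 calls by camera were lost with an estimated correlation (adjusted p = 0.473 to 0.907).

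The genes named at 4 h as not passing were the bitter taste receptor gene Tas2r137 (2.64 ± 0.56; at least 1.43-fold higher), Spink1 (2.72 ± 0.60; at least 1.87-fold), Ankrd66 (1.55 ± 0.29; at least 1.61-fold), Tyw3 (0.70 ± 0.14) and Zfp873 (0.64 ± 0.13). Tas2r137 was above background on 3 of 3 oleic acid arrays, Spink1 on 2 and Ankrd66 on 1, and each on 0 of 2 serum arrays. The folds of Spink1 and Ankrd66 therefore take in oleic acid arrays where the gene was not above background. At unadjusted p under 0.05, 763 genes stood against 1259 by chance. All 21 liver list members were higher at 4 h, at a median of 1.84 (limma camera adjusted p = 0.252 with an estimated correlation), with Alb at -6.09 in serum 4 h replicate 2. The call of ENSMUST00000079163 was lost with limma's arrayWeights (adjusted p = 0.0617), with normexp correction, where its difference was -0.58, and in 5 other fits, the strict filter left it untested, and without serum 4 h replicate 2 no gene passed.

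At 18 h (n = 2 and 2), heat shock, unfolded protein response, neutrophil and immediate early lists had lower medians in oleic acid mice. Both serum mice lay on slide 4 and both oleic acid mice on slide 5, so slide and treatment cannot be told apart within this time. All 16 heat shock genes were lower, at a median of -0.33, with Hspa1a, an inducible HSP70, at -0.61 ± 0.21. Unfolded protein response genes had 18 of 19 members lower (median -0.35), with the endoplasmic reticulum proteins Sdf2l1 at -0.89 ± 0.28 and Creld2 at -0.67 ± 0.16. Neutrophil and monocyte markers had 12 of 14 lower (median -0.82), with S100a9 at -1.35 ± 0.50 and S100a8 at -1.21 ± 0.53, opposite in sign to 1.5 h. Immediate early genes had 25 of 30 lower (median -0.43), with Npas4 at -0.93 ± 0.32, Egr1 at -0.90 ± 0.32 and Fos at -0.85 ± 0.38.

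Other called lists at 18 h were ribosomal proteins (22 of 22 lower, median -0.25), respiratory chain subunits (23 of 24 lower, -0.18), microglia markers (15 of 19 lower, -0.34), HIF targets (21 of 26 lower, -0.18), barrier genes (15 of 19 lower, -0.20), erythroid genes (9 of 10 lower, -0.34) and cerebellum markers (12 of 12 higher, 1.55). Gabra6 lay at -2.85 in serum 18 h replicate 1 and at 2.01 in replicate 2. None of the 11 calls by camera held with an estimated correlation (adjusted p = 0.455 to 0.859). Adjusted over the list alone, 6 unfolded protein response, 3 heat shock and 1 HIF member passed. No gene passed limma's adjusted p, and 1832 had an unadjusted p under 0.05. The smallest unadjusted p among named genes were those of Ceacam12 (-3.92 ± 0.63; at least 3.62-fold lower), the Wnt modulator gene Sfrp4 (0.61 ± 0.12), Ghdc (1.21 ± 0.25), the chromatin protein gene Hmgn1 (-0.58 ± 0.13) and the cell cycle factor gene E2f4 (1.97 ± 0.44; at least 2.53-fold higher). With a slide block, which compares the treatments only through other times, 8 genes passed.

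At 24 h (n = 2 and 3), Il1b differed by 0.86 ± 0.33 and Pdk4, an inhibitor of pyruvate oxidation, by 0.40 ± 0.18. The choroid plexus list held Slco1a5, an organic anion transporter, at 1.02 ± 0.30, and the water channel gene Aqp1 at 0.85 ± 0.23, and 2 of its members passed when adjusted over the list alone, as did 1 ion and water transport gene. Its median was 0.07, with 11 of 16 members higher. Hypothalamic neuropeptides had 10 of 12 lower at a median of -0.59, and Hcrt lay at -3.01 in oleic acid replicate 2. Both lists were called by camera at the preset correlation but not with an estimated one (adjusted p = 0.907 and 0.843).

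Named genes at 24 h, none past the test, were the granzyme gene Gzmf (-3.61 ± 0.75; at least 3.03-fold lower), Spata31d1b (-2.35 ± 0.50), the aromatase gene Cyp19a1 (-2.20 ± 0.47), Gpha2, a glycoprotein hormone subunit (-2.21 ± 0.49), and Cmbl (-0.43 ± 0.10). No gene passed limma's adjusted p, and 1657 had an unadjusted p under 0.05. Without the requirement that a probe be measured on all arrays, which was added after the data were examined, 2 transcripts known only by identifiers passed at 24 h (differences of -4.66 ± 0.76 and -3.58 ± 0.36, limma adjusted p = 0.0486 and 8.36e-05). Pituitary hormone transcripts were high in 1 of the 2 serum and 2 of the 3 oleic acid mice. With slide as a fixed block 80 genes passed, without serum 24 h replicate 2, the only mouse of this time on slide 2, 58, and without the 3 arrays with the highest Prl, 71. Cyp19a1 stayed lower in these 3 fits, at -3.36 under the slide block and -3.62 without the highest Prl. All 3 fits rest on the same 1 serum mouse, replicate 1, and are not independent. The fit without the highest Prl also keeps only 1 oleic acid mouse, replicate 2.

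Averaged over the 6 times (n = 14 and 17), the genes with the smallest unadjusted p were mostly erythroid. Hbb-bt differed by -0.73 ± 0.16, Alas2 by -0.72 ± 0.16, Hba-a1 by -0.67 ± 0.16 and Hba-a2, the second alpha globin gene, by -0.63 ± 0.14, folds of 1.66, 1.65, 1.59 and 1.55. The fifth, Tomm20l, differed by 0.30 ± 0.07. The erythroid list had 9 of 10 members lower, at a median of -0.47, and 5 members passed when adjusted over the list alone. None passed limma's adjusted p over all genes (0.998 for each), and 1148 genes had an unadjusted p under 0.05. The mean erythroid score differed by -0.37 ± 0.10 and was lower at 5 of 6 times (permutation p = 0.00306; 0.107 when adjusted over the 35 lists). By time, the score differed by -0.73, -0.17, -0.77, 0.01, -0.48 and -0.08.

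**Figure D2:**
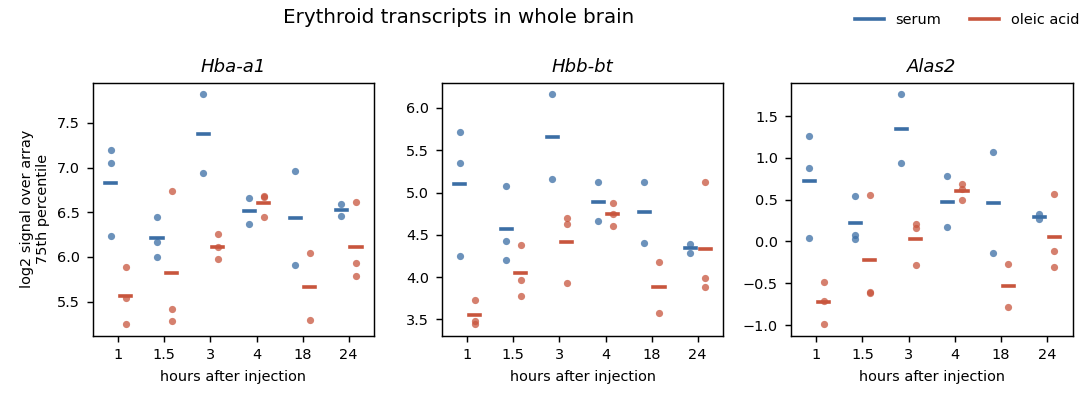
Log2 signal relative to the array's 75th percentile (vertical axis) against hours after injection (horizontal axis) for the globin genes Hba-a1 and Hbb-bt and for Alas2; each point is 1 mouse and each bar a group mean. At 1 h all 3 oleic acid mice lay below all 3 serum mice for each gene, and at 4 h the groups overlapped.

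Heat shock genes were lower in all 16 members for the mean effect, at a median of -0.10, with Hspa1a at -0.14 ± 0.08 (permutation p of the score = 0.0207; 0.363 when adjusted over the lists). Camera called 7 lists at the preset correlation, all lower: erythroid, heat shock, hypothalamic neuropeptides (12 of 12), oligodendrocyte (13 of 16), respiratory chain (22 of 24), ribosomal (19 of 22) and unfolded protein response (17 of 19) genes. None held with an estimated correlation, at adjusted p = 0.430 for erythroid, 0.455 for heat shock and 0.473 to 0.843 for the others. With slide as a fixed block the erythroid score differed by -0.37 ± 0.15, but the list tests no longer passed even before adjustment over the lists (limma camera p with an estimated correlation = 0.0588 for erythroid and 0.224 for heat shock genes, against 0.00527 and 0.0111 without the block). For heat shock genes the same was seen with scaling to the median (0.107) and with tissue scores as covariates (0.0733). With the slide block, 35 genes passed limma's test, led by the chromatin organizer gene Satb1 (-1.65 ± 0.09, against -0.37 without the block). Under the block the slides are linked only through groups split over 2 slides. The differences at 1.5, 18 and 24 h then rest on single arrays, and the blocked mean leans on them. Without the 3 arrays of slide 2, 9 genes passed, and without serum 24 h replicate 2, 4.

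Genes that handle fatty acids did not stand apart in the oleic acid brains. Angptl4, a lipase inhibitor induced by fatty acids, differed by between -0.47 and 0.12 over the 6 times, and the lipid droplet gene Plin2 by between -0.10 and 0.03. The mean score of PPAR targets differed by -0.02 (permutation p = 0.606; 0.867 adjusted over the lists), and that of desaturation and lipogenesis genes, which include Scd1, by -0.01 (permutation p = 0.719; 0.867 adjusted). Of the fixed panel, 36 of 40 genes were measured. None of their 216 single-time tests passed limma's adjusted p, 26 had an unadjusted p under 0.05, and the largest difference was that of Ccl2 at 1.5 h. Il6, Tnf and Cxcl1 were above background on at most 1, 0 and 3 arrays and were not tested.

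Whether the oleic acid effect differed between times was tested in 2 ways. The early minus late difference passed limma's adjusted p for 0 genes (1471 at unadjusted p under 0.05), and the F-test of any difference between times for 0 (1371 at unadjusted p under 0.05). For early minus late, camera called 8 lists at the preset correlation, among them choroid plexus (median -0.20), ribosomal (0.21) and neutrophil (0.43) genes, and none with an estimated correlation (adjusted p = 0.790). Across genes, which are not independent replicates, the differences at 2 times correlated at between -0.32 and 0.26 (median -0.04, 15 pairs of times). Without serum 24 h replicate 2, 16 genes passed for early minus late and 19 for any difference, and with slide as a fixed block 26 and 38.

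Time after injection and anaesthesia was compared in serum mice as the background against which oleic acid was read. Map3k6, a stress-activated kinase gene that glucocorticoids induce in brain, was highest at 4 h, with a log2 level of 1.41 ± 0.15 (SD, n = 2) against -0.24 ± 0.17 at 18 h. The clock repressor gene Ciart, the forkhead factor gene Foxo3, and Hmgb2 and H1f2, which encode chromatin proteins, peaked at 3 h, and Tcim, Spdef, Nanos2 and the cold-induced gene Cirbp at 4 h. These genes were among those with the smallest limma adjusted p (3.07e-05 for Hmgb2 to 0.000542 for Nanos2) of 2626 genes (10.4%) that passed.

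In oleic acid mice, 1769 genes varied with time, or 35 with slide as a fixed block, 84 with slide as a random block and 696 without oleic acid 4 h replicate 1. Of the 1769, 916 were shared with serum mice, against 185 for independent lists, but both tests share each gene's variance and slide followed time in both treatments, so the excess cannot be read as a shared effect of time. With slide as a fixed block 125 genes passed in serum mice, 93 of them among the 2626. Of the 125, 74 were also among the 1769 that passed in oleic acid mice without the block, where slide followed time. The genes named above all passed with the block (limma adjusted p from 0.00418 to 0.0255). Without serum 18 h replicate 1, 678 genes passed. Serum mice at 4 h and at 18 h (n = 2 each) lay on slide 4, and 233 genes differed between them, 159 higher and 74 lower at 4 h. Ciart was higher by 2.15 ± 0.29, Foxo3 by 1.84 ± 0.26, Map3k6 by 1.65 ± 0.17 and Cirbp by 1.07 ± 0.14. Without serum 18 h replicate 1, 39 genes passed this contrast.

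Glucocorticoid-response genes were the list with the most members varying with time. Of 29 measured members, 12 passed the serum time test over all genes and 18 when adjusted over the list alone, 10 of the 12 were highest at 4 h, and all 12 also varied in oleic acid mice. Between 4 h and 18 h in serum mice, 28 of 29 were higher at 4 h, at a median of 0.86 (limma camera p = 0.00333 with an estimated correlation, 0.117 adjusted over the lists). The metallothionein gene Mt2 was higher by 1.42 ± 0.22, the kinase gene Sgk1 by 1.79 ± 0.41, Pdk4 by 0.98 ± 0.20 and the transcription factor gene Klf9 by 0.86 ± 0.16. The cell cycle inhibitor gene Cdkn1a differed by 1.22 ± 0.33, not past limma's adjusted p. In oleic acid mice, which lay on different slides at these times, the list median was 0.68. Fkbp5, a glucocorticoid receptor chaperone gene, stood at 1.96 ± 0.98 (SD, n = 2) in serum and 1.99 ± 0.46 (SD, n = 3) in oleic acid mice at 4 h. Without serum 4 h replicate 1 the median in serum mice was 0.39 (limma camera p = 0.0663 with an estimated correlation), and with slide as a fixed block 8 members passed the serum time test when adjusted over the list alone and 1 over all genes.

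**Figure D3:**
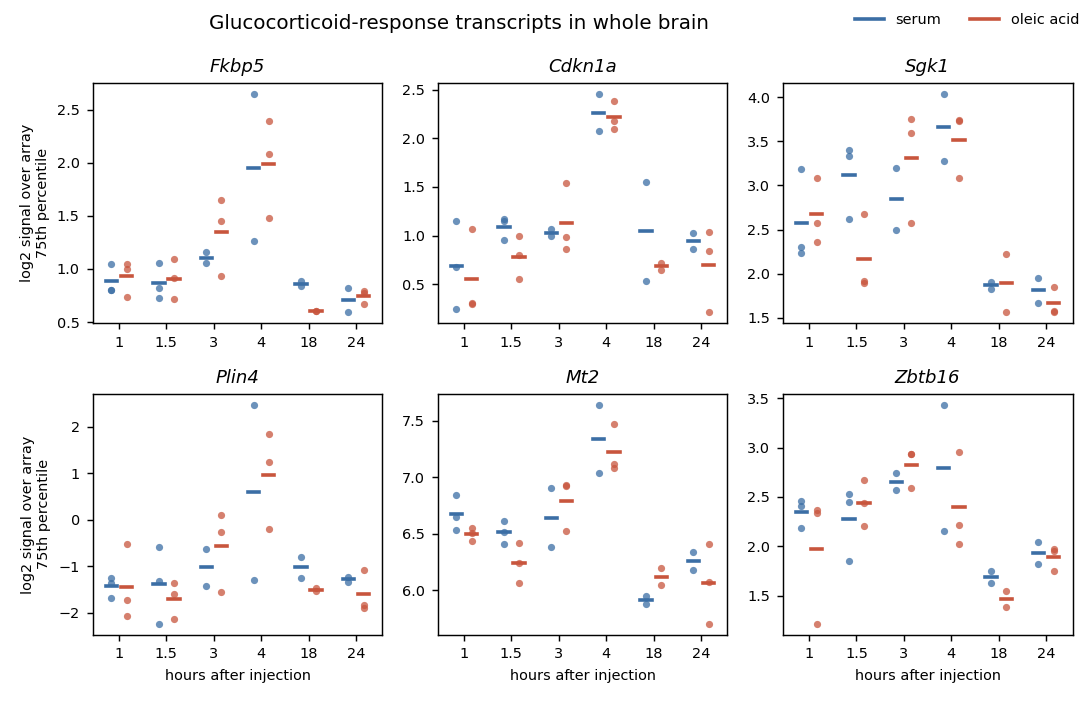
Log2 signal relative to the array's 75th percentile (vertical axis) against hours after injection (horizontal axis) for Fkbp5, Cdkn1a, Sgk1, Plin4, Mt2 and Zbtb16; each point is 1 mouse and each bar a group mean. Group means of Fkbp5, Cdkn1a, Sgk1, Plin4 and Mt2 were highest at 4 h in serum and in oleic acid mice. For Plin4 the serum mean at 4 h rests on replicate 1, at 2.46, as replicate 2 lay at -1.29.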

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

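Both explanations of the liver pattern below were tested only after it had been seen, and so was the choice of 1 h and 4 h, 1 of 15 pairs of times.

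The liver list had a lower median with oleic acid at 1 h and a higher one at 4 h. It passed at neither time (limma camera adjusted p = 0.0543 and 0.252 with an estimated correlation). The oleic acid effect on the liver list score was -2.59 at 1 h and 1.64 at 4 h, a difference of -4.23, the 1 result that stood out because 2 times differed in their effect. An effect of oleic acid that lowers these transcripts at every time was argued against by a permutation test of the largest difference between times over all 15 pairs, with the common effect removed (permutation p = 0.00510), and by a lower score at 4 of 6 times only. It took the place of an exact permutation test of 1 h against 4 h alone (p = 0.005), run first, which did not allow for the choice of that pair. The later p does, but it does not allow for the choice of the liver list, which was written after liver genes were seen at 1 h. Liver RNA carried into some brain samples is a candidate explanation: within groups, 10 liver members outside the 100 genes with the lowest p at 1 h correlated over arrays at a median of 0.52 (0.522), against 0.190 for the 99th percentile of 1000 random lists. These lists were matched in mean level only, and genes regulated together would exceed them too. The correlation therefore cannot tell carried-over RNA from shared regulation. Alb and Fgb, the fibrinogen beta chain gene, were well above background on 29 and 27 of the 31 arrays, at median levels of -0.55 and -2.85. In oleic acid 1 h replicate 2 they lay at -5.68 and -7.59, and in serum 4 h replicate 2 at -6.09 and -7.33. Detection on most arrays therefore does not show that part of these signals comes from the brain itself, which was not tested. A response of the brain or of blood at single times stays open, and no biological explanation was tested separately. The liver score also followed the lung score over the 31 arrays (Pearson's r = 0.754, permutation p = 1e-05, the smallest they can give, 6e-05 adjusted over 6 relations; Spearman's rho = 0.519, permutation p = 0.00307, 0.00921 adjusted), at r = 0.506 without the 2 arrays farthest from the median and at 0.911, 0.280, 0.689 and 0.710 within slides 1, 3, 4 and 5, while slide 2 held too few arrays.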

How the results depend on the processing

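Signal over background and 2 or 3 mice per group limit these counts, and each is the number of genes past limma's adjusted p unless lists are named. The fits with tissue scores, without chosen arrays or with missing spots kept, and those for time in oleic acid mice and for serum 4 h minus 18 h, were chosen after seeing the data. Scaling to the median moved the median difference of all genes by up to 0.20 (0.196) on the log2 scale. The cause was not tested for any change below unless one is given.

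The counts to compare with are 0 at 1, 1.5, 3, 18 and 24 h, 1 at 4 h, 0 for the mean effect, early minus late and any difference between times, 2626 and 1769 for time in serum and oleic acid mice, 233 for serum 4 h minus 18 h, and 46 lists. With slide as a fixed block they were 30 (1.5 h), 2 (3 h), 2 (4 h), 8 (18 h), 80 (24 h), 35 (mean), 26 (early minus late), 38 (any difference), 125 and 35 (time) and 26 lists. In that fit the slides are linked only through groups split over 2 slides, so 1.5, 18 and 24 h rest on single arrays. With slide as a random block, 24 h gave 1, and time 192 and 84. With scan date as a block, 1.5, 3 and 4 h gave 1, 1 and 2. Limma's arrayWeights, whose fit stopped before convergence, gave 1 (1 h), 1361 (1.5 h), 2 (3 h), 0 (4 h), 120 (18 h), 3 (24 h), 1 (any difference), 9975 and 7200 (time), and 7 panel tests.

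Replicate numbers were shared between groups, with no clear sign that they paired the mice. After group means were removed, 3 of the 14 same-number pairs of oleic acid and serum arrays correlated above 0.1, within a range from -0.62 to 0.39. These values are not independent: in groups of 2 mice the deviations mirror each other, and both pairs at 18 h gave -0.044. The lowest and the highest, both at 1.5 h, compared arrays of different slides. The check therefore cannot exclude a pairing. With a block by replicate number, counts were 1 at 4 h, 0 for every other oleic acid comparison, and 56 lists. The 1 at 4 h was another transcript, as ENSMUST00000079163 had an adjusted p of 0.145 (limma).

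Scaling to the median gave 1 (18 h), 2 (24 h), 1244 and 828 (time) and 63 (4 h minus 18 h). Normexp gave 0 (4 h) and 126 (4 h minus 18 h) and reversed Ect2 (-0.14) and Trim30d (-0.00218) at 3 h. Quantile normalization gave 2 (4 h) and 1 (any difference), and the deposited log2 values gave 1 (1.5 h), 2 (18 h) and 1 (24 h). Without a filter, time gave 1155 and 954, with more genes tested. The strict filter, eBayes with trend and robust options, and a fit to that time alone gave 0 at 4 h, and the last gave 2 (3 h) and 3 (18 h). The mean of all probes gave 2 (24 h), and an estimated correlation 0 lists. With missing spots kept, 24 h gave 2, both known only by probe or region identifiers, early minus late 1 and any difference 1.

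Tissue scores as covariates gave 5 (1.5 h), 1 (3 h), 0 (4 h), 550 and 563 (time) and 60 (4 h minus 18 h). Without the 3 arrays of slide 2, counts were 7 (1.5 h), 3 (3 h), 3 (4 h), 84 (24 h), 9 (mean), 16 (early minus late), 44 (any difference) and 4297 (serum time). Without the 3 arrays with the highest Prl they were 1 (3 h), 71 (24 h), 10 (mean), 27 (early minus late), 27 (any difference), 1274 and 851 (time). Without the 4 with the lowest Gabra6 they were 0 (4 h), 806 and 426 (time).

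Leaving out each of the 31 arrays in turn gave these ranges. Counts ran from 0 to 30 at 1 h (without serum 1 h replicate 3), 0 to 159 at 1.5 h (serum 1.5 h replicate 3), 0 to 6 at 3 h (serum 3 h replicate 1), 0 to 4 at 4 h (0 without serum 4 h replicate 2, 4 without replicate 1), 0 to 2 at 18 h (serum 18 h replicate 2) and 0 to 58 at 24 h (serum 24 h replicate 2; 10 without its replicate 1 and 5 without oleic acid 1.5 h replicate 1). The mean effect ran from 0 to 4, early minus late from 0 to 16 and any difference from 0 to 19, each highest without serum 24 h replicate 2. Serum time ran from 678 (serum 18 h replicate 1) to 4545 (oleic acid 1.5 h replicate 1), oleic acid time from 696 (oleic acid 4 h replicate 1) to 2711 (oleic acid 1 h replicate 3), serum 4 h minus 18 h from 39 (serum 18 h replicate 1) to 337 (oleic acid 1 h replicate 3), and lists from 41 to 60. Where 1 array was left in a group, it was assumed to vary like the other groups. Of the values for single genes and lists across all fits, 4238 kept direction and side of the threshold, 53 came to pass, 629 no longer passed and 2 reversed. ENSMUST00000079163 stayed lower at 4 h in every fit that tested it, which the strict filter did not.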

Other observations

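The tests of the erythroid pattern, the test of slide for the glucocorticoid pattern, the added organ lists, and the relation between list scores were chosen only after the results were seen.

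Single genes of other groups also differed between serum mice at 4 h and 18 h. As lists, the 4 groups below passed limma's camera at the preset correlation (adjusted p = 3.19e-07 to 0.000253), but none with an estimated correlation. Heat shock genes were lower at 4 h in 15 of 16 members, at a median of -0.26 (limma camera adjusted p = 0.138 with an estimated correlation, the value of each of the 4 lists here). Chordc1, an HSP90 co-chaperone gene, stood at -0.81 ± 0.15 and past the adjusted test. Unfolded protein response genes were lower in 15 of 19 members, at a median of -0.19, and Creld2 and Manf passed, at -0.90 ± 0.16 and -0.91 ± 0.19. Neutrophil and monocyte markers were lower in 12 of 14 members, at a median of -0.93, with the granule protein genes Camp at -1.38 ± 0.35 and Ltf at -2.09 ± 0.55. Neither passed the adjusted test over all genes, while 6 members passed over the list alone. Organ transcripts were also lower at 4 h in these mice: Alb lay at -1.72 and -6.09, against -0.40 and 0.28 at 18 h. Sftpc lay at -1.06 and -1.36, against 0.33 and -0.31. Any link to the neutrophil shift was not tested. Endothelial markers were lower in 13 of 18 members, at a median of -0.37, with the angiopoietin receptor gene Tek at -1.18 ± 0.25 and the transporter gene Slco1a4 at -0.59 ± 0.13, both past the test. In oleic acid mice the medians between the same times were -0.01 (heat shock), -0.06 (unfolded protein response), 0.00 (0.000930, neutrophil and monocyte) and -0.05 (endothelial), but these mice lay on slide 4 at 4 h and on slide 5 at 18 h, so that contrast is mixed with slide. The serum shifts rest on 2 mice per time, and the same 2 serum mice at 18 h stand behind the lower heat shock, unfolded protein response and neutrophil values with oleic acid at 18 h. The heat shock median was -0.10 without serum 4 h replicate 1, -0.15 without serum 18 h replicate 1, -0.16 with tissue scores as covariates and -0.33 with scaling to the median, and in each of these fits the limma camera p with an estimated correlation, before adjustment over the lists, was above 0.05 (0.120, 0.0600, 0.0997 and 0.126).

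Kidney and muscle transcripts showed no list shift. At 1 h the added kidney list had 4 of 7 members lower at a median of -0.04, the muscle list 6 of 9 higher at 0.14, and the lung list 6 of 7 lower at -1.56, with limma camera adjusted p = 0.882, 0.970 and 0.0712 with an estimated correlation. The liver and kidney scores had r = 0.473 over the 31 arrays (permutation p = 0.0104, 0.0312 adjusted over 6 relations) and r = 0.315 without the 2 arrays farthest from the median, with Spearman's rho = 0.368 (permutation p = 0.0424, 0.0636 adjusted). Within slides 1, 3, 4 and 5 that r was 0.653, -0.0954, 0.591 and -0.0139.

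Erythroid transcripts were lower in oleic acid brains on average. Whether RNA carried over from other organs, or uneven dissection, was the whole cause cannot be told. With tissue scores as covariates the erythroid score still differed by -0.298 ± 0.125. But the list was singled out after the results were seen, and its permutation p adjusted over the lists was 0.107. A remaining difference in such a list cannot decide against a cause. The covariates also cover the cerebellum, pituitary, hypothalamus, liver and lung lists only. The test with tissue scores took the place of a test of slide that had been run first. In that test the score differed by -0.374 ± 0.152 with a slide block. The erythroid and liver scores had r = 0.430 over the 31 arrays (permutation p = 0.0157, 0.0314 adjusted over 6 relations), with Spearman's rho = 0.523 (permutation p = 0.00306, 0.00921 adjusted), and r = 0.220 without the 2 arrays farthest from the median. Within slides 1, 3, 4 and 5 that r was 0.824, 0.548, -0.355 and 0.194. The erythroid and lung scores had r = 0.393 (permutation p = 0.0278, 0.0417 adjusted), 0.184 without the 2 farthest, and 0.924 on slide 1, which held all 1 h mice. Their rho was 0.336 (permutation p = 0.0658, 0.0789 adjusted). RNA from other organs is therefore not excluded, at 1 h above all. Less blood in the oleic acid samples cannot be told apart from a change in erythroid transcripts, since the platelet score differed by -0.123, neither near the erythroid value nor at 0 or above, and the neutrophil score by 0.01 (0.00579), with permutation p = 0.0340 and 0.000260 for their differences from the erythroid score. Oleic acid itself as the cause stays open, because the permutation p adjusted over the lists was 0.107. The difference ranged from -0.411 to -0.328 when each array was left out, and within slides the list median was -0.91 at 1 h, 0.21 at 1.5 h (1 array of each), -1.10 at 3 h, 0.05 at 4 h and -0.11 at 24 h.

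Of 29 glucocorticoid-response transcripts, 12 varied with time in serum mice and 15 in oleic acid mice, and 10 of the 12 had their highest serum level at 4 h. For 4 h against 18 h only, a difference between slides was argued against by slide 4, which held both serum groups. There the serum median difference was 0.856, though with 2 mice per time. Without serum 4 h replicate 1 it was 0.393, and the argument no longer holds. Serum mice at the other times lay on other slides, so a peak at 4 h over all times is not separated from slide. With slide as a fixed block, 1 member passed the serum time test over all genes and 8 over the list alone. A difference in dissection between 4 h and 18 h was also argued against. With tissue scores as covariates the median was 1.08 (limma camera p = 0.000672 with an estimated correlation). This rests on the same 2 serum mice per time, and Gabra6 lay at 1.89 and -7.31 in those at 4 h. With these covariates 9 members passed the serum time test, against 12 without. Lowered body temperature after anaesthesia cannot be told apart from other effects of time: the cold-induced gene Rbm3 differed by 0.498 ± 0.170, not past limma's adjusted p (0.212), while Cirbp passed (0.000468). Over all times Rbm3 did vary in serum mice (limma adjusted p = 0.0195), and its mean level was highest at 4 h in both treatments, at 3.59 in serum and 3.74 in oleic acid mice. Stress, anaesthesia, time of day and handling are not separated by the design, and no biological explanation other than body temperature was tested.

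Regrouping the arrays gave the following. At 1 h, 10 splits are too few for a share under 0.05, with 0 genes for the real split and 0 for the highest other (10 of 10 as large, as a real 0 always gives), and 12 lists, adjusted within that comparison, against 9 (1 of 10). At 1.5 h the 10 splits are too few as well, with 0 genes against 1536 (10 of 10) and 7 lists against 7 (2 of 10). The split with 1536 genes set both slide 2 arrays and oleic acid replicate 2 against the rest, so it points to a structure of the samples, and the fit with a slide block gave 30 for the real split. Of 100 regroupings within times, all 100 gave as many genes as the real 0 for the mean effect (highest other 2), for early minus late (1754) and for any difference between times (22), which any real count of 0 gives and which tests nothing. For the lists of the mean effect, 46 gave as many as the real 7 (highest other 16), so chance is not excluded. The regrouping with 1754 genes placed both 1.5 h arrays of slide 2 in the oleic acid set and again points to a structure of the samples, while the next highest gave 6. For time in serum mice, 1 of 100, the real one, gave 2626 genes and the highest other gave 36, so chance can be excluded, though slide followed time here and the blocked count was 125.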
